A study of Rattus norvegicus with 2 samples.

How the data were processed

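RNA from 2 groups was sequenced after ribosomal RNA depletion and a digest with 16 units of RNase R, an enzyme that degrades linear RNA, for 15 minutes at 37 °C, per the labels' protocols. The libraries were strand-marked. There was 1 sample for each of 2 groups, made from 3 animals each; the labels do not state whether RNA was pooled. Per the submitters' processing notes, CASAVA 1.8 and BWA were used and the build was rn6, with no role given for any of them. The circRNA caller and its read minimum are not given in the sources used here. The positions in the table did not match the rat and its genome build is not named in it.

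The deposited values are headed TPM in the file headers, but were treated as RPM, that is scaled to the circular junction reads of the library. Both columns summed to nearly the same total, and above the placeholder of 0.001 every value (100%) was a whole multiple of 1 step per library to within 0.001 reads, whatever the circRNA, so the values hold no length term. Dividing by the step gave reads, totalling 159941 in the control and 151685 in the bone cancer pain library. The lowest listed value was 2 reads. The placeholder was taken as 0 reads; since a circRNA with 1 read may not have been listed, no fold and no upper limit is given for circRNAs absent from 1 library. Host sums hold listed reads only, so their ratios and intervals leave out reads on junctions that were not listed; for host genes with no circRNA listed in both libraries (137 of the 3113 with 10 or more reads, beside those absent from 1 library), sums are given without a ratio, though they count in the numbers higher or lower and in list medians.

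Each ratio is the share of reads in the bone cancer pain library over that in the control, with an exact conditional binomial (Clopper-Pearson) 95% interval. Shares have exact binomial intervals. Ranks and medians used log2 ratios with 0.5 reads added to each library. A circRNA or host gene was called higher or lower by size, at a ratio of 2 or 0.5 with 0.5 reads added, and with 10 or more reads over both libraries. These are sizes and not tests. Names of small RNAs such as small nucleolar RNAs were not counted as host genes. Host sums used circRNAs with 1 host gene, leaving out 407 with several, 362 with none and 45 whose host name had been turned into a date. In the counting draws, both libraries were drawn 100 times from Poisson distributions with the same pooled shares, and values under 2 reads were removed.

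Before the data were examined, the comparisons, the other settings to be tried, the rule for named genes and 20 lists were fixed. The rule named the 8 circRNAs with the highest and the 8 with the lowest ratio among those with 20 or more reads and a host gene, the 8 with the most reads, the 5 highest and 5 lowest host genes, and the 2 highest and 2 lowest members of each list with 20 or more reads. COL8A1 is named because the series design names it. The 20 lists hold 769 genes: MAPK/ERK, PI3K/AKT/mTOR, glutamate and postsynaptic, presynaptic, ion channels, GABA and glycine, neurons, astrocytes, microglia and macrophages, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial cells with pericytes and fibroblasts, skeletal muscle, blood and bone marrow, cell division and carcinoma, neuroinflammation and NF-kB, circRNA formation and RNA binding, chromatin, protein kinase C with calcium and cAMP, and conserved circRNA hosts. They were written as rat symbols. After the table and a first set of list medians had been seen, they were matched to its human symbols in upper case, with 13 set by hand. A list's median was placed among 10000 random lists of the same size drawn within 10 classes of abundance.

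The other settings were further scalings (median of ratios and a trimmed mean of ratios, TMM, trimming 30% of ratios and 5% of abundances, both coded directly), minimums of 5 and 20 reads, 2 reads added, a ratio of 1.5, an interval excluding 1, 2 or more reads in each library, the control thinned to the depth of the other library, and medians over single circRNAs. In simulated data, 200 features were changed, all picked among those with 20 or more measured reads over both libraries. Of these, 96% of 100 circRNAs set 3-fold higher and 93% of 100 set 5-fold lower were recovered among 17260. For host genes, 95% and 95% were recovered among 5157. Recovery of features with 10 to under 20 reads was not simulated. Among unchanged features with 10 or more simulated reads, 628 of 5393 circRNAs (11.6%) and 222 of 2896 host genes (7.67%) passed 2-fold by counting error. Because the identifiers are human, circRNAs on chromosome Y and of the genes that mark X inactivation were left out of the results. The library totals used for scaling were taken before this step, so any such reads count in them. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used. Exon and intron annotation was not used here. Some results that the rule names are not reported here.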

Results

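Circular RNAs (circRNAs), which are closed loops made when a downstream splice site joins an upstream one, were sequenced in a rat model of bone cancer pain. Per the labels, animals with bone cancer pain had live Walker256 cells, a rat breast carcinoma line, injected into the tibia, and controls received the same cells boiled for 20 minutes. The groups had 3 animals each and were killed 21 days after surgery. The labels give the source in 2 ways that disagree, as cancer cells from ascites and as spinal cord cells of the injected rats. There was 1 library per group, and the table held 1 column of values for each, so there were no replicates and no test between conditions. Each ratio below therefore compares 2 libraries. The 95% intervals are exact and cover counting error only.

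The control library held 159941 circular junction reads and the bone cancer pain library 151685. Across both, 17260 circRNAs were considered, of 5157 host genes. The identifiers in the table were human. In all, 9315 circRNAs carried a human circBase identifier (circBase is a catalogue of published circRNAs), and they took 82.4% of the control reads (exact binomial interval 82.2 to 82.5) and 79.9% of the bone cancer pain reads (79.7 to 80.1). Of all circRNAs, with or without such an identifier, 538 lay on chromosomes 21 and 22, which the rat gene table used here (assembly GRCr8) lacks. Of 4513 host genes with a rat gene of the same name, 6.05% (5.37 to 6.78) were on the same chromosome number as that gene. The gene symbols and positions below are therefore those of the table, which match the human style and not the rat build in the submitters' processing notes, and both groups are named as the libraries so labelled.

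Few of the listed neuronal and oligodendrocyte markers had a circRNA. No spinal cord library was compared, so the shares below do not tell the source of the RNA. Of the 32 neuronal markers, 3 had a circRNA, among them NAV3, which had 105 control and 97 bone cancer pain reads (ratio of bone cancer pain to control 0.97, interval 0.73 to 1.30), and NRG1, a growth factor for glia, which had 22 and 14 (0.67, 0.32 to 1.37). Of the 40 oligodendrocyte and myelin markers, 10 had a circRNA. Together these made 13 of 72 genes (18.1%, 9.98 to 28.9). Shares were smaller for skeletal muscle (2 of 22, 9.09%) and for blood and bone marrow (1 of 29, 3.45%). Several other lists not tied to neural cells had larger shares. For cell division and carcinoma cells, 27 of 42 genes had a circRNA (64.3%, 48.0 to 78.4), a share like that of MAPK/ERK (43 of 66, 65.2%), PI3K/AKT/mTOR (26 of 41, 63.4%) and protein kinase C, calcium and cAMP (30 of 46, 65.2%) and below that of circRNA formation and RNA binding (33 of 43, 76.7%) and chromatin regulators (50 of 52, 96.2%).

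The first question was how many circRNAs each library held. The control library had 12178 circRNAs and the bone cancer pain library 12322. Both libraries shared 7240, which was 41.9% of all circRNAs (41.2 to 42.7). The 4938 circRNAs listed only for the control library had a median of 3 reads and took 10.9% of its reads. The 5082 listed only for the bone cancer pain library also had a median of 3 reads and took 11.9%. The median span between the ends was 5405 bp in the control and 5874 bp in the bone cancer pain library. With both libraries drawn from the same pooled shares, a median of 9022.5 circRNAs fell in both (8919 to 9166 over 100 draws), against the 7240 measured.

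The most abundant circRNAs differed by less than 2-fold between the libraries. A circRNA of ASPH, an aspartyl hydroxylase of the endoplasmic reticulum (hsa_circ_0084615, chromosome 8, 62593527 to 62596747), had the most reads, with 2743 in the control and 2049 in the bone cancer pain library (0.79, 0.74 to 0.83). A circRNA of the chromatin regulator ASXL1 (hsa_circ_0001136, chromosome 20, 30954187 to 30956926) had 1871 and 2030 reads (1.14, 1.07 to 1.22). Junctions of RPPH1, the RNA component of ribonuclease P, were next, with 1241 and 1511 reads for the most abundant form (1.28, 1.19 to 1.39). That form had no circBase identifier, and whether it is circular RNA was not tested. The circRNA of CORO1C, an actin-binding coronin (hsa_circ_0000437), was at 0.68 (0.62 to 0.75) and that of PTTG1IP (hsa_circ_0001200) at 0.67 (0.60 to 0.74). The circRNA of SPECC1 (hsa_circ_0000745) was at 1.36 (1.23 to 1.51). Those of CAMSAP1, a microtubule minus-end protein (hsa_circ_0001900, 1.05, 0.96 to 1.15), and SOGA2 (hsa_circ_0000825, 0.96, 0.88 to 1.05) had intervals that include 1. The 10 circRNAs with the most reads took 7.54% of control and 7.46% of bone cancer pain reads.

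The second comparison asked which circRNAs differed between the libraries. Those with the largest ratios were listed in 1 library and absent from the other. Among circRNAs with a host gene, the highest in the bone cancer pain library was that of SPC24, a kinetochore protein (hsa_circ_0007223, chromosome 19, 11258494 to 11258789), with 45 reads and none listed in the control. It was followed by a circRNA of ZZZ3 (chromosome 1, 78097535 to 78107340, 35 reads) and junctions of RPPH1 (35 and 34 reads). Next were a circRNA of ALDH1A2, an enzyme of retinoic acid synthesis (hsa_circ_0035443, 28), and a junction of RMRP, the RNA component of ribonuclease MRP (27). After these came a junction of MYH9, the heavy chain of a nonmuscle myosin (chromosome 22, 36682764 to 36684934, 27). The last named was a circRNA of RGS12, a regulator of G protein signalling (hsa_circ_0006091, 26).

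Another junction of MYH9 (chromosome 22, 36694965 to 36696280) had the most reads among circRNAs listed in the control library and absent from the bone cancer pain library, at 150. A junction of the actin crosslinker FLNA (chromosome X, 153577730 to 153581184) had 42 reads there. The matrix glycoprotein gene SPARC (chromosome 5, 151054173 to 151055762) had 52, and PTMS 44. Also listed there were circRNAs of WDR62, a spindle pole protein (hsa_circ_0003139, 24), of the myosin MYO1E (hsa_circ_0005211, 22) and of the Mediator subunit MED14 (hsa_circ_0006712, 22). No fold is given for any of these, since the lowest listed value was 2 reads and a circRNA that is not listed can still have had 1.

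Of 5415 circRNAs with 10 or more reads over both libraries, 936 were at least 2-fold higher in the bone cancer pain library, 919 at least 2-fold lower and 3560 between. Under median of ratios scaling, which shifts the log2 ratios by 0.08, the balance turned to 853 higher and 998 lower. This shift is the difference in library totals, since the median circRNA listed in both libraries had equal reads. Under TMM, with a shift of -0.002, 936 were higher and 892 lower. The interval also excluded 1 for 582 of the higher and 553 of the lower. With both libraries drawn from the same pooled shares, a median of 630 circRNAs passed 2-fold (576 to 693 over 100 draws), against the 1855 measured. With 1 library per condition, a difference of this kind has no replicate check.

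**Figure D1:**
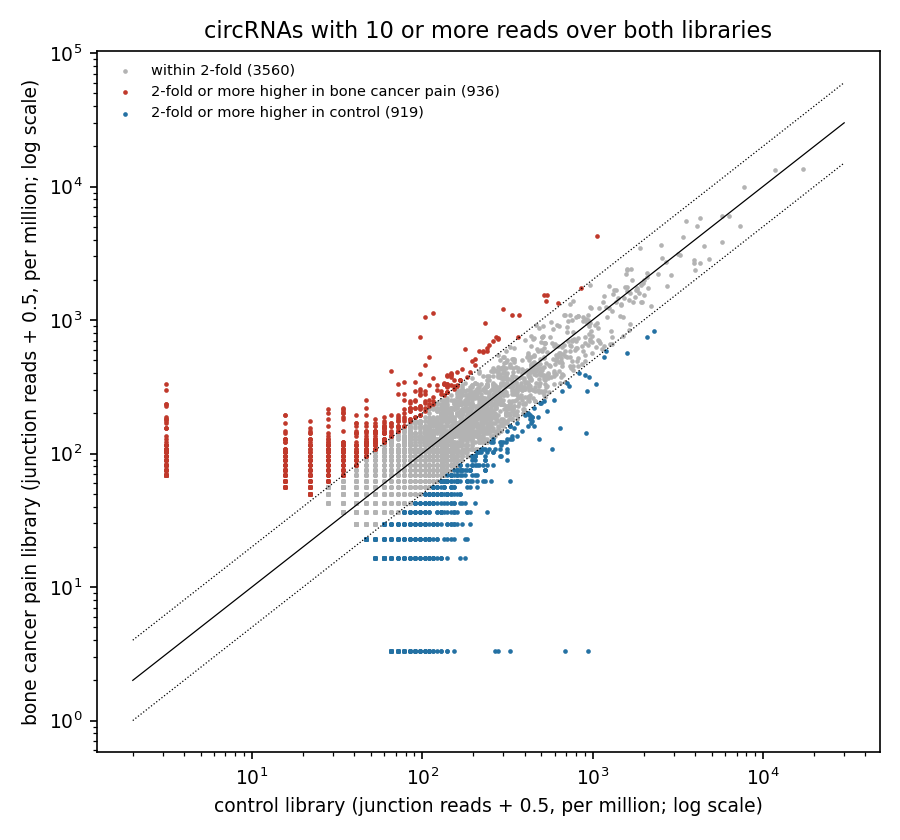
Junction reads with 0.5 added, scaled to RPM, in the control library (x axis, log scale) and the bone cancer pain library (y axis, log scale) for 5415 circRNAs with 10 or more reads over both; dotted lines mark 2-fold. The 936 circRNAs higher (red) and 919 lower (blue) lie on or outside the dotted lines, and circRNAs absent from 1 library form the rows along the lower and left sides.

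Summed over the circRNAs of each host gene, RMRP had 29 reads in the bone cancer pain library and none listed in the control. FAM135A had 20 and none. SPC24 had 45 and 2, on different junctions, so no ratio is given. ARHGAP5, a GTPase-activating protein, had 25 and 2 (ratio 13.2, 3.29 to 114.8), and CAB39, a partner of the kinase LKB1, 18 and 2 (9.49, 2.27 to 84.3). In the other direction, ESCO1, a cohesin acetyltransferase, had 28 control reads, MED14 22 and MDGA1 21, with none listed in the bone cancer pain library. The mitochondrial protease PITRM1 had 23 control reads and 2 (10.9-fold lower, 2.69 to 95.4), and the mitochondrial fission protein DNM1L 22 and 2 (10.4-fold lower, 2.56 to 91.5), tied with MCAM and TBC1D5, which had the same reads. The SPC24, RMRP and MED14 sums rest on the junctions given above, without which they are 2 control reads and none for SPC24, none and 2 for RMRP, and none in either library for MED14. Of 3113 host genes with 10 or more reads, 425 were at least 2-fold higher, 433 at least 2-fold lower and 2255 between; 34 of the higher and 49 of the lower had reads in both libraries but no circRNA listed in both. A median of 261.5 passed 2-fold (217 to 310) in the 100 draws, against 858 measured.

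The series points to ERK signalling and to Col8a1. Circular junction reads of a host gene measure neither its linear mRNA nor its protein, nor the activity of ERK. The values below therefore describe circRNAs only. In the MAPK/ERK list, 5 of 31 host genes with 10 or more reads were at least 2-fold higher, 5 lower and 21 between. The median log2 ratio was 0.08, at percentile 70.8 of 10000 random lists matched for abundance. The kinases MAPK8 (8 and 27 reads; 3.56, 1.57 to 9.06) and MAP4K4 (18 and 43; 2.52, 1.42 to 4.64) were highest among members with 20 or more reads. The negative regulator SPRED1 (16 and 4; 0.26, 0.064 to 0.82) and the exchange factor RAPGEF1 (42 and 17; 0.43, 0.23 to 0.77) were lowest. COL8A1, a collagen, had 30 control and 20 bone cancer pain reads (0.70, 0.38 to 1.28). The MAPK/ERK median turned negative with a minimum of 20 reads (-0.18), over single circRNAs (-0.37) and with circBase identifiers only (-0.17).

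In the PI3K/AKT/mTOR list, 3 of 19 host genes were higher, 1 lower and 15 between, with a median of -0.03 (percentile 51.7). FOXO1, a transcription factor under AKT, had 10 and 31 reads (3.27, 1.56 to 7.47) and MTOR 7 and 15 (2.26, 0.87 to 6.55). RPTOR, a subunit of the mTOR complex, had 62 and 26 (0.44, 0.27 to 0.71) and GSK3B 125 and 85 (0.72, 0.54 to 0.95).

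Of the 20 lists, 13 had at least 3 members with 10 or more reads. Of these, 3 had medians outside the middle 95% of their random lists, where 0.65 would fall by chance. The markers of endothelial cells, pericytes and fibroblasts had the highest median, 0.90 (percentile 99.8), with 5 of 10 members higher and none lower. The basement membrane collagens COL4A1 (14 and 42 reads; 3.16, 1.69 to 6.27) and COL4A2 (16 and 43; 2.83, 1.56 to 5.39) were highest among members with 20 or more reads. Of the COL4A2 reads, 20 were on 1 junction without a circBase identifier and with none listed in the control; without it COL4A2 had 16 and 23 (1.52, 0.77 to 3.07), and the list median was 0.51 (percentile 95), inside the middle 95%. The matrix genes FN1 (24 and 63; 2.77, 1.71 to 4.63) and COL3A1 (24 and 59; 2.59, 1.59 to 4.36) and the receptor TEK (4 and 13; 3.43, 1.06 to 14.4), named after their values were seen, were the other 3. The receptor FLT1 (13 and 7; 0.57, 0.19 to 1.53) and the collagen COL5A2 (19 and 12, with no circRNA listed in both) were lowest. Without FN1, the member with the most reads, the median was 0.44 and inside the middle 95% of its random lists (percentile 89.9), as it was with a minimum of 5 reads (0.44, percentile 90.3) or of 20 (0.44, percentile 91.0). Leaving out any of the 5 higher members had the same effect, while leaving out any of the other 5 kept the median outside. With an even number of members, the median can only move to the lower or the upper middle value.

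The neuroinflammation and NF-kB list had the lowest median, -0.78 (percentile 1.63), with 4 of 8 members lower and none higher. Among members with 20 or more reads, the transcription factor STAT3 (28 and 8 reads; 0.30, 0.12 to 0.68) and the kinase IKBKB, which activates NF-kB (68 and 27; 0.42, 0.26 to 0.66), were lowest. RELB, a subunit of NF-kB (22 and 9; 0.43, 0.17 to 0.97), and the cytokine receptor subunit IL6ST (8 and 2, with no circRNA listed in both), named after their values were seen, were the other lower members. TRAF3 (23 and 30; 1.38, 0.77 to 2.48) and TGFBR2 (20 and 15; 0.79, 0.38 to 1.62) were highest among members with 20 or more reads. Without IKBKB, the member with the most reads, the median was -0.39 and inside the middle 95% of its random lists (percentile 17.9), as it was without any of the other 3 lower members and over single circRNAs (-0.39, percentile 17.8).

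In the chromatin regulator list, 11 of 46 members were higher, 4 lower and 31 between, with a median of 0.28 (percentile 99.0). The DNA demethylase TET2 had 5 and 30 reads (6.33, 2.43 to 20.9) and the remodeller CHD9 21 and 77 (3.87, 2.36 to 6.60). The histone deacetylase HDAC9 had 36 and 10 (0.29, 0.13 to 0.60) and SETD5 16 and 5 (0.33, 0.094 to 0.94). With rat symbols put in upper case and no others matched, the list had 44 members and a median of 0.20 (percentile 96.3), inside the middle 95%. Leaving out 1 member put it inside for 23 of the 46 members (percentiles from 97.0 up to 99.8 over all).

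The list of genes known for abundant conserved circRNAs had 6 of 40 members higher and 5 lower, with a median of 0.14 (percentile 95.2). Its highest were ARHGAP5, given above, and the sodium-calcium exchanger SLC8A1 (67 and 206 reads; 3.24, 2.45 to 4.34). Its lowest among members with 20 or more reads was HDAC9, given above, followed by MBTD1 and SIRT5 with the same reads (15 and 6 each; 0.42, 0.13 to 1.15). Genes for cell division and carcinoma cells had a median of 0.19 (percentile 87.1), with 3 of 23 higher and 2 lower. POLA1, a subunit of DNA polymerase alpha, had 9 and 25 reads (2.93, 1.32 to 7.13) and the kinesin KIF20B 32 and 71 (2.34, 1.52 to 3.67). The spindle motor KIF11 had 16 and 5 (0.33, 0.094 to 0.94) and the condensin subunit NCAPG 49 and 30 (0.65, 0.40 to 1.04).

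Factors of circRNA formation and RNA binding had a median of 0.14 (percentile 77.2), with 5 of 23 higher and 4 lower. ZC3H13 (15 and 42 reads; 2.95, 1.6 to 5.73) and the splicing factor SRSF1 (8 and 22; 2.90, 1.24 to 7.53) were highest. YTHDC2 (15 and 6; 0.42, 0.13 to 1.15) and TNRC6A (95 and 41; 0.46, 0.31 to 0.66) were lowest among members with 20 or more reads. The protein kinase C, calcium and cAMP list had a median of -0.08 (percentile 39.4), with 5 of 20 higher and 4 lower. In it, the phospholipase PLCE1 had 20 and 40 reads (2.11, 1.20 to 3.81) and PDE1C 28 and 42 (1.58, 0.96 to 2.65). The kinases PRKD1 (21 and 4; 0.20, 0.050 to 0.60) and PRKCE (64 and 29; 0.48, 0.30 to 0.75) were lowest.

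The neural lists had few members with reads. For glutamate receptors and the postsynaptic density, 1 of 5 was higher, none lower, and the median was 0.08 (percentile 57.4). The scaffold SHANK3 had 12 and 27 reads (2.37, 1.16 to 5.14) and HOMER1 9 and 11 (1.29, 0.49 to 3.52). DLG1, which is not restricted to neurons, had 850 and 549 (0.68, 0.61 to 0.76), and CAMK2D 35 and 23 (0.69, 0.39 to 1.21). With DLG1 holding most of the reads, the sum over the list was lower in the bone cancer pain library (0.71, 0.64 to 0.79). The median was the value of GRIP1, with 5 reads in each library and no circRNA listed in both. Its sign therefore reflects only the difference in library totals. The presynaptic list had a median of -0.12 (percentile 38.2), with 1 of 7 lower, STX1A (22 and 6; 0.29, 0.095 to 0.73). In that list RIMS1 (127 and 90; 0.75, 0.56 to 0.99) was next lowest among members with 20 or more reads, and UNC13B (30 and 41; 1.44, 0.88 to 2.39) and PPFIA1 (119 and 114; 1.01, 0.77 to 1.32) were highest.

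For ion channels the median was 0.04 (percentile 57.3) over 4 members, 1 of them higher, the potassium channel KCNQ5 (2 and 15 reads; 7.91, 1.84 to 71.3), named after its value was seen. TRPM7 had 99 reads in each library (1.05, 0.79 to 1.41) and CACNA2D1, a calcium channel subunit, 21 and 20 (1.00, 0.52 to 1.95). The oligodendrocyte and myelin list had a median of -0.23 (percentile 24.4), with 1 of 5 lower, the phosphodiesterase PDE4B (135 and 62; 0.48, 0.35 to 0.66). KIF1B had 47 and 26 reads (0.58, 0.35 to 0.96), PDE8A 82 and 90 (1.16, 0.85 to 1.58) and DOCK9 12 and 11 (0.97, 0.39 to 2.39).

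The other 7 lists had under 3 members with 10 or more reads and have no median. In the astrocyte list, with 6 of 25 genes bearing a circRNA, NHSL1 had 27 and 15 reads (0.59, 0.29 to 1.14). In the microglia and macrophage list, with 5 of 32, RUNX1 had 17 and 7 (0.43, 0.15 to 1.10) and LYN 12 and 13 (1.14, 0.48 to 2.74). The GABA and glycine list had a circRNA for 3 of 29 genes. The oligodendrocyte precursor list had a circRNA for 2 of 18 genes, skeletal muscle for 2 of 22, and blood and bone marrow for 1 of 29.

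**Figure D2:**
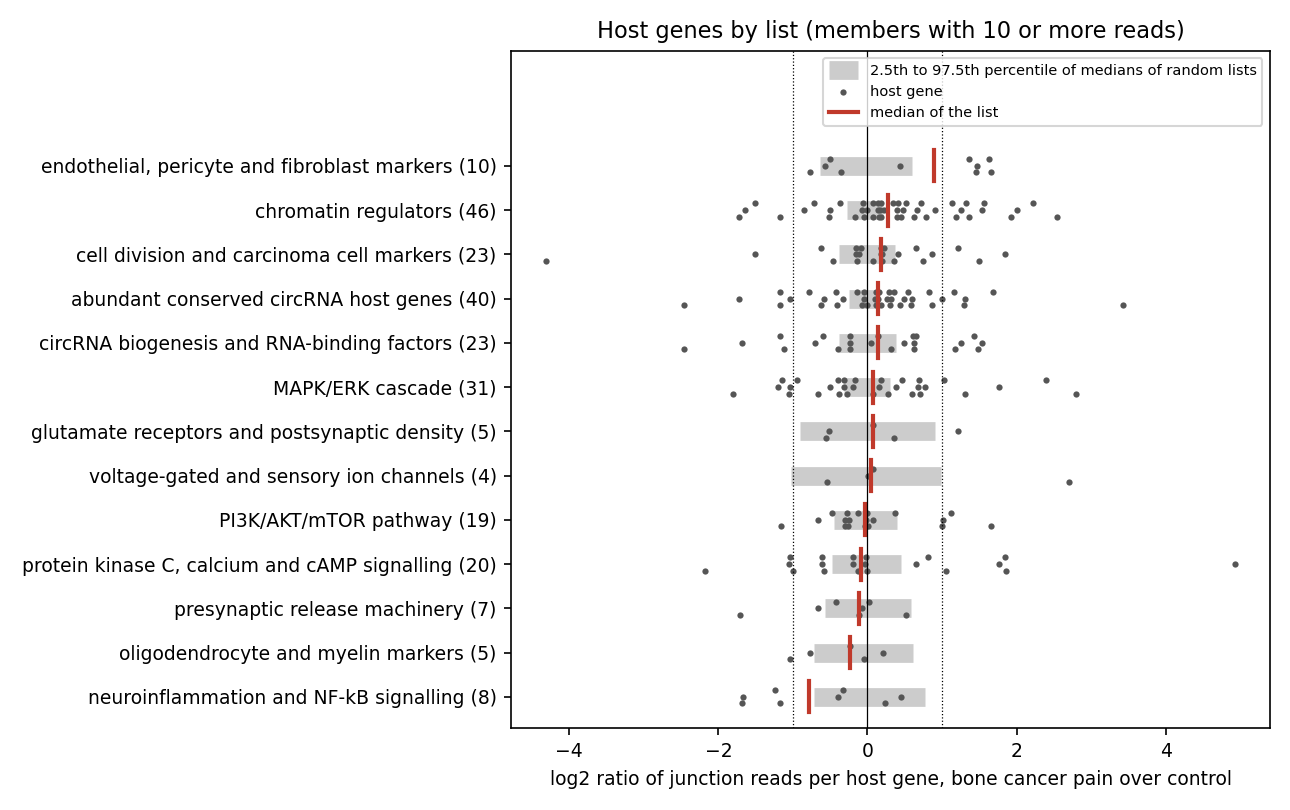
Log2 ratio of junction reads, bone cancer pain over control (x axis), for the host genes (points) with 10 or more reads in each of 13 lists, with the list median (red) and the middle 95% of medians of random lists (grey); numbers in parentheses are members. The medians of the endothelial, pericyte and fibroblast list (0.90), the chromatin list (0.28) and the NF-kB list (-0.78) lie outside the grey bars; each falls inside under another setting (0.44 without FN1, 0.20 with upper-case rat symbols alone, and -0.39 without IKBKB).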

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

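The tests on coordinates, on neural lists, on the share of reads with a human identifier and on circBase identifiers of circRNAs in 1 library were chosen after the result was seen; those on named kinds of hosts without a rat gene and on counting error were written before.

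In a series labelled rat, 9315 circRNAs carried a human circBase identifier and 538 lay on chromosomes 21 and 22. Rat coordinates under human-style names are argued against by the 3.14% of circRNAs on sequences that the rat gene table lacks. For rat spinal cord RNA aligned to a human genome, the prediction was at least as large a share of neuronal and oligodendrocyte as of cell division genes. The shares with a circRNA were 18.1% and 64.3%, and signalling lists reached the latter too. This cannot decide, since no spinal cord library was compared. Marker lists of skeletal muscle (9.09%) and of blood and bone marrow (3.45%) were low too. For rat RNA of any cell type aligned to a human genome, the test took 189 clone-named, LINC, antisense or ZNF hosts without a rat gene of that name. Of their circRNAs, 27.8% reached 10 reads (23.0 to 33.1), against 32.1% of circRNAs whose host has a rat gene of that name. A much lower share had been predicted. This cannot decide either, since a missing name does not show that the rat lacks the sequence. A table made from human cells stays open: the 81.2% of reads on human identifiers does not bear on it, since any RNA aligned to a human genome could give such a share, and no biological explanation was tested.

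A set of 24 circRNAs had 20 or more reads in 1 library and none listed in the other, 14 of them in the bone cancer pain library and 10 in the control. Counting error is argued against, since 0 of 100 draws gave as many. Of the 24, 37.5% (18.8 to 59.4) had a circBase identifier, against 84.0% (82.6 to 85.3) of 2809 circRNAs with like reads in both libraries. Junctions that are not circular RNA, which may arise in library making or from linear RNA, could give such a lower share. Single junctions, such as those of MYH9, SPARC and RMRP, were not tested. A circRNA made in few cell types could also be missing from the catalogue, so a difference between the conditions stays open and untested.

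More circRNAs passed 2-fold, 1855, than counting error gives, with 0 of 100 draws reaching that number. A difference between libraries of the same condition and a difference between the conditions cannot be told apart, because there is 1 library per condition.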

How the results depend on the processing

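The alternatives limited to circBase identifiers, without 1 list member, with absent list members set to 3 reads, with upper-case symbols only and without circRNAs of 20 or more reads in 1 library only were chosen after seeing the data. No named circRNA or gene past 2-fold changed sign under another scaling or with 2 reads added. That outcome was fixed in advance and shows no stability. The scalings shifted log2 ratios by at most 0.08, and adding equal reads to both libraries only draws a ratio towards equal reads. The limits were 1.5 times the reported value for a count and a 95% interval for a ratio, share or list median (over its members; the range with under 6). Of the values under an alternative, 204 for the comparisons and 303 for named items stayed within them, and 18 moved; the interval of a list median is wide, so sign changes and lost places outside the random lists count as within. Of 169 list medians, 45 equalled the reported one. By construction of the filter, a minimum of 5 reads gave 1998 circRNAs higher and 1958 lower, and 648 and 657 host genes; a minimum of 20 reads gave 358 and 342 circRNAs, and 214 and 219 host genes. A ratio of 1.5 gave 1512 and 1526 circRNAs, and 741 and 768 host genes. An interval that excludes 1 gave 582 and 553 circRNAs. Median of ratios scaling gave 853 and 998 circRNAs and 409 and 443 host genes; TMM gave 936 and 892, and 441 and 421. Detection at 5 or more reads gave 5992 circRNAs in the control and 5952 in the bone cancer pain library. Counted over circRNAs and not reads, the share with a circBase identifier was 60.7% and 58.7%. The medians of 6 lists (MAPK/ERK, PI3K/AKT/mTOR, glutamate, ion channels, cell division, circRNA formation) changed sign, in 13 combinations of list and setting; each of these medians was at most 0.19 in size in the reported setting. Leaving out any 1 member moved the endothelial, pericyte and fibroblast median between 0.44 and 1.36 and the NF-kB median between -1.17 and -0.39. Without 1 member, the endothelial median fell inside the middle 95% of its random lists for 5 of 10 members left out, the NF-kB median for 4 of 8 and the chromatin median for 23 of 46. These even splits follow from the median. Each list has an even number of members, so leaving out 1 gives either the lower or the upper middle value. Restricted to circBase identifiers, the endothelial list had 2 members (median 0.82, percentile 82.1). Setting absent members to 3 reads could move no median, since only 2 members were absent from a library and both lie far from their medians. Without circRNAs of 20 or more reads in 1 library only, the endothelial median was 0.51. No paired analysis was possible because each group had 1 library. The alternatives that need replicate columns, or a unit without reads, were not run for the same reason or because the table gave reads. Depth limits low circRNAs: 41.8% of those in the control and 41.9% of those in the bone cancer pain library had 2 or 3 reads.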

Other observations

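Among 708 host genes with 100 or more reads, a rule chosen after the values were seen, 21 were at least 2-fold higher in the bone cancer pain library and 16 lower. The cadherin FAT1 was highest, with 25 control and 178 bone cancer pain reads (7.51, 4.92 to 11.9), followed by the linker histone HIST1H1C (38 and 162; 4.50, 3.14 to 6.58) and the co-chaperone STIP1 (45 and 174; 4.08, 2.92 to 5.79). The vitamin D hydroxylase CYP24A1 had 40 and 143 (3.77, 2.64 to 5.50). Among those lower were ZFAND6 (113 and 28; 3.83-fold lower, 2.51 to 6.01) and PILRB (168 and 50; 3.19-fold lower, 2.31 to 4.46). The AP-1 subunit FOSL1 had 85 and 30 (2.69-fold lower, 1.75 to 4.22), the Golgi protein TMEM165 357 and 138 (2.45-fold lower, 2.01 to 3.01) and the co-chaperone DNAJB6 124 and 48 (2.45-fold lower, 1.74 to 3.49).

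Junctions within 3 noncoding RNAs were also picked after their values were seen. RPPH1 had 1448 control and 2325 bone cancer pain reads over 8 junctions (1.69, 1.58 to 1.81). None of these junctions had a circBase identifier, and whether they are circular RNA was not tested. Its form from 20811288 to 20811559 on chromosome 14 had 169 and 641 (4.00, 3.37 to 4.77), while the most abundant form, from 20811283 to 20811529, was at 1.28. MALAT1 had 15 and 36 reads (2.53, 1.35 to 4.98), 23 of the latter on 1 junction of 65267947 to 65268121 on chromosome 11 with none listed in the control. Its other junctions summed to 15 and 13 (0.91, 0.40 to 2.06), among them hsa_circ_0002540 with 9 and none listed. RMRP had none listed and 29.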
